A study of Mus musculus with 4 samples.

How the data were processed

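Lung RNA of 4 groups of mice was profiled for miRNAs: newborns and adults, each kept for 72 h in room air or in 95% oxygen, with 1 library per group. Per the labels' protocols, the right lung was taken after the pulmonary artery was flushed, and nursing dams alternated between both atmospheres so that they were not injured. Total RNA was reverse transcribed with Megaplex primer sets A and B, preamplified and read with TaqMan assays, per the labels' protocols. Each library covers 2 cards of 384 wells, 768 wells in all, of which 750 hold miRNA assays and 18 hold controls. Groups were taken from the sample titles.

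The authors deposited threshold cycles (Ct) and, for each well, Ct minus the Ct of snoRNA202 (delta Ct). Both are on a log2 scale that falls as RNA rises, per the file headers, and a difference of 1 cycle is 2-fold only at perfect amplification. The software, threshold and baseline settings are not given in the sources used here. A well with no crossing holds a Ct of 40, which the deposited delta Ct carries through as a number. The Ct values of both deposited tables are identical. In 3 libraries the reference is the snoRNA202 of the well's own card. In the adult room air library the second card's 384 wells use the first card's snoRNA202 (13.4 cycles in place of 13.7, a difference of -0.225), and 1 first-card well uses the second card's. The 4 U6 wells of each card hold 1 averaged value. No depth in reads exists for this assay, and the range of Ct stands in its place: 267, 291, 263 and 261 miRNA assays had a Ct of 25 or below in neonatal room air, neonatal hyperoxia, adult room air and adult hyperoxia, and the median detected Ct was 24.2, 24.0, 24.2 and 24.2. Repeat measurements exist only for control RNAs, so the precision of late assays was not measured; the results give the shares of 2-fold differences by Ct.

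The level used here is the deposited delta Ct with its sign turned, so that a difference between libraries is a log2 ratio. An assay was compared between 2 libraries where its Ct was 35 or below in both, and counted when it differed by at least 1 log2 unit (2-fold). With 1 library per group these differences have no test and no p-value. The technical SD of a difference comes from U6, snoRNA135, U87 and Y1, each measured on both cards and set against its own card's snoRNA202, as the root mean square of the gap between cards divided by the square root of 2.

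For age over both oxygen conditions, and for oxygen over both ages, an additive model of age and oxygen was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) to the 426 assays detected in all 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom per assay and 1.57 prior degrees of freedom. It assumes that oxygen acts alike at both ages, and an error of the reference RNA, which shifts all assays of a card together, is not in its standard errors. Nothing says whether a library is 1 animal or a pool, so p-values measure only the spread between these samples, which may be technical. The model was tested on simulated data with 60 of 426 assays changed with age and the same noise SD of 0.40 for every assay. It recovered 31.7% of changes of 1 log2 unit, 93.3% of 2 and 100% of 4, and called 0 unchanged assays for age. No oxygen change was planted, so recovery for oxygen was not measured. In this balanced design the SE of an assay is the same for age and for oxygen. In the data the SE varied between assays, and these shares do not carry over to the noisier ones. For example, miR-29b, at 5.49 ± 1.11 log2 for age, was not called.

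Before the data were examined, the tests, the thresholds above, 23 miRNA lists with 189 members, the alternatives and the rule for named miRNAs were fixed. The lists were the families of let-7, miR-15 and miR-16, miR-29, miR-34 and miR-449, miR-200, miR-30, miR-181, and miR-130 and miR-301, the clusters of miR-17 with its paralogs, Dlk1-Dio3 and the embryonic miR-302, miR-367 and miR-290, other imprinted fetal growth loci, and miRNAs of airway and alveolar epithelium, smooth muscle, endothelium, fibroblast and mesenchyme, leukocytes, inflammation, hypoxia and redox response, erythroid cells, cardiac and skeletal muscle, liver and brain. No assay matched 13 members. Star forms (passenger strands) and assays named for rat were not list members. A list with 3 or more measured members was given as its median and that median's percentile among 10000 random lists of the same size, drawn per member from the 40 assays nearest in mean level. The draws did not take the card into account. The percentile describes these libraries and is not a test: 80 were computed, 5 lay below the central 95% and 7 above it, and of 200 simulated unchanged lists 8.5% lay outside. miR-34a, miR-93, miR-155 and miR-200a are each in 2 lists.

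Named are, per comparison, the 10 highest and 10 lowest differences among assays with a Ct of 32 or below in both libraries, and up to 5 per direction with a Ct of 30 or below in one library and over 35 in the other, given as a bound against Ct 35. List members, control RNAs and the 10 largest differences between the hyperoxia effects of both ages (Ct of 32 or below in all 4) may also be named. Assays that fell or rose with age outside the lists, miR-423-5p and miR-219 among the smallest p-values for oxygen, the pairs of mouse and rat-named assays and the wells discussed in the closing section were chosen after their values were seen. Assay names are those of the files without the mouse prefix. Of the assays, 641 are named for mouse and 108 for rat, and the latter are called rat-named. Whether their sequences match the mouse miRNAs was not checked.

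The alternatives were centring each library on the mean of the assays detected in all 4, U6 as reference, snoRNA135 and snoRNA202 as reference, each card centred on its median, Ct limits of 32 and 40, and eBayes with a trend. After seeing the data 5 more were added: each card's own snoRNA202, leaving out row L of the first card, a Ct limit of 25, list medians with each card centred, and the count of assays called alike under all 6 normalizations. The 6 are the authors' values, each card's own snoRNA202 and the first 4 alternatives. Gene neighbours were taken from the RefSeq annotation of GRCm38.p6, in which 515 mouse assays matched 1 miRNA gene and 126 matched none or several. No coordinates are given, since no source used here names the authors' build. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.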

Results

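Levels of microRNAs (miRNAs) were measured by quantitative PCR in lungs of newborn and adult mice kept for 72 h in room air or in 95% oxygen (hyperoxia), to follow lung development and the response to hyperoxia. Newborns were 3 days old at collection and adults were 2 months old. Each of the 4 groups had 1 library, so a difference between 2 libraries has no replicate check. The labels do not say how many animals a library holds. Values below are log2 relative levels against the small nucleolar RNA snoRNA202, with higher values for more RNA. Of 750 miRNA assays, 477 were detected (threshold cycle, Ct, of 35 or below) in neonatal room air, 507 in neonatal hyperoxia, 468 in adult room air and 468 in adult hyperoxia. In all 4 libraries 426 assays were detected. The plant miRNA ath-miR159a, a negative control, crossed no threshold in any library.

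The only repeat measurements were 4 control RNAs present on both cards of a library, namely U6, snoRNA135, U87 and Y1. From the gaps between cards, the technical SD of a difference was 0.26 log2 for neonatal hyperoxia against room air and 0.33 for adult hyperoxia against room air. It was 0.65 for adult against neonatal room air and 0.95 for adult against neonatal hyperoxia. These SDs rest on 4 RNAs and leave out variation between animals. Row L of the first card, 24 wells that include miR-511, miR-532-5p and miR-574-3p, was out of step in the adult room air library. Its Ct values correlated at r = 0.302 across wells with the mean of the other 3 libraries, against 0.769 or more in every other row of every library.

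Adult lung held far less of the imprinted miRNAs than neonatal lung. In room air, 29 of the 31 measured members of the Dlk1-Dio3 cluster, a large group of maternally expressed miRNAs active in fetal and perinatal tissue, were at least 2-fold lower in the adult library. The list median was -5.31 log2. In hyperoxia, 32 of 32 were at least 2-fold lower, with a median of -5.59. Among 10000 random lists matched on level, both medians lay at percentile 0. In a limma model of age and oxygen over all 4 libraries, 26 of 29 fitted members fell with age at a Benjamini-Hochberg adjusted p under 0.05, and 27 fell when adjusted over the list alone.

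The largest fitted falls in that cluster were those of miR-370, which fell by 10.10 ± 0.62 log2 (SE; limma, Benjamini-Hochberg adjusted p = 0.0152), and miR-431, which fell by 9.81 ± 0.29 (limma, adjusted p = 0.0152). In the same fit miR-412 (-9.51), miR-433 (-8.57), miR-376a (-7.28), miR-487b (-6.69), miR-541 (-6.62) and miR-382 (-6.21) fell. Members nearest 0 were miR-381 at -1.01 (limma, adjusted p = 0.194) and miR-494, which fell by 2.47. The remaining uncalled members were miR-543 at -2.80, whose well is in row L, and miR-673-5p at -6.83. Imprinted loci elsewhere in the genome went the same way. All 3 fitted members of that list fell, over all assays and when adjusted over the list alone: miR-335-5p, encoded in Mest (-4.66 log2), miR-335-3p (-4.21) and miR-296-5p, from the Gnas locus (-4.41). The room air list median was -4.57 and the hyperoxia median -4.25. miR-298, next to miR-296, was at -9.17 in room air. Both list medians stayed below 0 under all 6 normalizations tried.

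**Figure D1:**
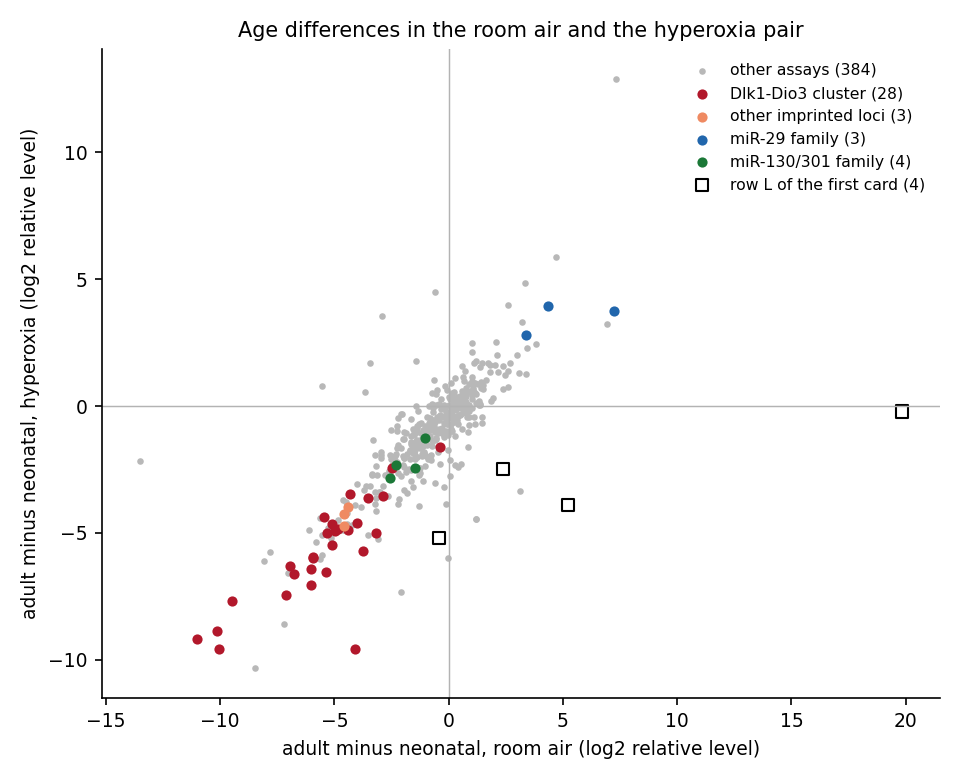
Adult minus neonatal log2 relative level in room air (x axis) against the same difference in hyperoxia (y axis), 1 point per miRNA assay detected in all 4 libraries. The Dlk1-Dio3 cluster lies at the lower left, with medians of -5.31 and -5.59 over its measured members, and the 3 miR-29 assays lie at the upper right; 4 assays of row L of the first card are marked with squares.

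The miR-29 family, which represses collagen and other matrix genes, was higher in adult lung. miR-29c rose with age by 4.15 ± 0.27 log2 (SE; limma, Benjamini-Hochberg adjusted p = 0.0160) and miR-29a by 3.09 ± 0.30 (limma, adjusted p = 0.0233). miR-29b was 7.22 log2 higher in adult room air and 3.76 higher in adult hyperoxia, and missed the threshold over all assays (limma, adjusted p = 0.0604). Over all assays 2 of 3 members rose, and 3 of 3 rose when adjusted over the list alone. The list median was 4.36 in room air and 3.76 in hyperoxia, above 0 under all 6 normalizations. Of the family's passenger strands miR-29a* rose by 3.26 log2, while miR-29c* at 1.67 (limma, adjusted p = 0.148) and miR-29b* at -0.47, which reached 1.07 under another normalization, were not called. The passenger strand miR-21* rose by 4.08. Other assays that rose included miR-338-3p by 2.85, miR-489 by 3.14, miR-22 by 2.20, miR-7a by 1.97, miR-99a by 1.58 and miR-10b, from a Hox cluster, by 1.46. A separate assay named for rat miR-10b was at -2.02 in room air, opposite to the mouse assay at 1.37. miR-1904 rose by 10.11 ± 1.76, the least precise of the rises.

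Over all 426 assays fitted, 19 rose and 119 fell with age (limma, Benjamini-Hochberg adjusted p under 0.05). The split depended on the reference: it was 99 up and 77 down with each library centred on its mean, 196 and 71 with U6, 50 and 112 with snoRNA135 and snoRNA202, and 136 and 84 with each card centred on its median. In a count chosen after the data were seen, 19 assays rose and 56 fell under every one of the 6 normalizations. Of these, 20 were Dlk1-Dio3 list members, 3 belonged to the other imprinted loci and 2 to the miR-29 family. Passenger strands and rat-named assays were not list members, so these counts leave out further falls of miRNAs of the Dlk1-Dio3 cluster. Examples are miR-411* (-7.89 log2), miR-376b* (-3.31) and rat-named miR-376a* (-6.78), miR-487b (-5.73) and miR-409-3p (-5.31). Apart from these, the 56 falls included miR-351 (-6.81 log2) and miR-503 (-5.18), neighbours on the X chromosome, miR-196a (-7.08), a Hox cluster miRNA, miR-135b (-5.59), and the skeletal muscle miRNA miR-206 (-3.02). By contrast, 8 assays were called up under one normalization and down under another.

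Lists with other known roles moved less, and some of their directions followed the reference. Families and clusters are named by their first miRNA. In the family of miR-130 and miR-301 (the miR-130 family), expressed in lung vessels, miR-301a (-2.70 log2) and miR-130b (-2.33) fell (limma; 2 of 4 members over all assays, 4 of 4 adjusted over the list alone). Its room air median of -1.89 turned to 0.75 with U6. In the miR-17 cluster and its paralogs, which promote proliferation, miR-18a fell by 1.64 (1 of 12 members, 0 adjusted over the list alone), and the room air median of -1.07 turned to 1.58 with U6 and to 0.07 with each card centred. In the family of miR-15 and miR-16, miR-15b (-1.59) and miR-322 (-2.18) fell (2 of 6; adjusted over the list alone 3 fell and 1 rose). miR-449a and miR-449c, miRNAs of multiciliated cells, fell, at -3.39 and -1.96 (2 of 6 in the miR-34 and miR-449 list on either adjustment), while miR-34a was 1.20 higher in adult room air and 0.11 higher in adult hyperoxia. That list's room air median of 0.95 and mean of -0.15 differ in sign.

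Among tissue lists, miR-214 (-3.004) and miR-199a-5p (-2.28) fell of the 5 fibroblast and mesenchyme members, whereas miR-10b rose. Of 7 airway and alveolar epithelium members, miR-205 (-2.23) and miR-182 (-1.67) fell. The endothelium list had 1 call of 3 (miR-218, fell by 1.85), the hypoxia and redox list 1 of 6 (miR-210, induced by low oxygen, fell by 2.71), the muscle list 1 of 5 (miR-206), the brain list 1 of 3 (miR-137, fell by 2.41) and the embryonic miR-302, miR-367 and miR-290 list 2 of 6 (miR-302b at -3.10 and miR-292-3p at -1.48, both of which fell). Counts for these 7 lists were equal when adjusted over the list alone. The fits of miR-199a-5p, miR-205, miR-182, miR-218, miR-210, miR-137, miR-292-3p, miR-15b, miR-18a, miR-322, miR-130b and miR-301a lay above 0 with U6. Of these, miR-15b, miR-18a, miR-182 and miR-292-3p are among the 8 assays called both ways, lower under 2 normalizations and higher under 1. The let-7, miR-200, miR-30 and miR-181 families and the leukocyte, inflammation, erythroid and smooth muscle lists had 0 calls on either adjustment on the snoRNA202 scale (limma); over all 426 assays 211 had an unadjusted p under 0.05. Under 4 of the 6 normalizations miR-30a, miR-30d, miR-21, miR-145, miR-142-3p and miR-142-5p were called higher in adults, under 3 miR-146a, miR-146b and miR-150, and under 2 let-7b, let-7c, let-7g, let-7i, miR-30b, miR-30c, miR-30e, miR-200a, miR-141, miR-223, miR-451, miR-143 and miR-181a. Of the other fitted members of these lists, 10 were called higher under 1, and miR-98, miR-212 and miR-144 under 0. The largest room air values of these lists included miR-146b at 1.94, miR-21 at 1.66, miR-30d at 1.51, miR-145 at 1.41, miR-144 at -1.39 and miR-142-5p, a leukocyte miRNA, at 1.18. The inflammation list had a room air median of 1.36 at percentile 99.1, with 3 of 5 members 2-fold higher and a median above 0 under all 6 normalizations. In hyperoxia its median was 0.02 and its mean -0.04, at percentile 86.4. The rat-named assay of its member miR-146b did not repeat the room air difference, at 0.13 against 1.94 on the mouse assay.

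**Figure D2:**
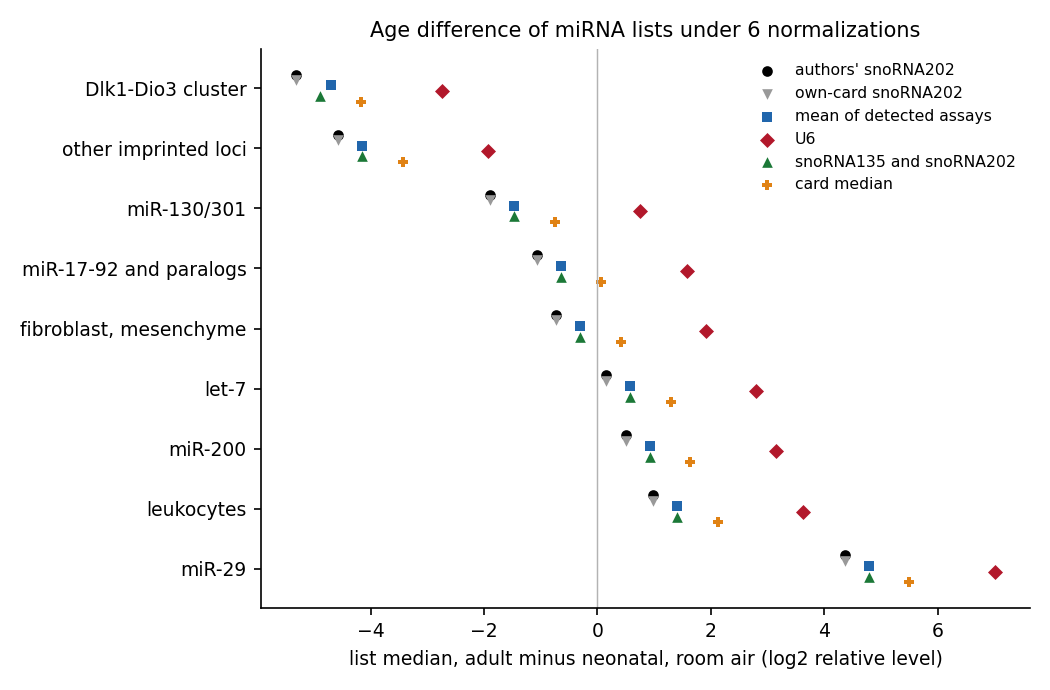
Median adult minus neonatal log2 relative level in room air of 9 miRNA lists (rows), with 1 symbol per normalization. The Dlk1-Dio3 median runs from -5.31 to -2.73 and stays below 0, the miR-29 median runs from 4.36 to 7.01, and the miR-130 and miR-17 medians cross 0.

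Between the room air libraries, 69 assays were at least 2-fold higher and 192 at least 2-fold lower in the adult, of 435, with a median of -0.72 log2. Besides those named above, the largest differences were miR-1896 at -13.49, an assay named for rat miR-632 at -8.47, and one named for rat miR-376a* at -7.82. miR-511 at 19.83 and miR-582-3p at 5.21 come from row L. With a Ct of 30 or below, 10 assays were detected only in the adult and 23 only in the neonate. The 5 earliest in the adult, with Ct 35 as the bound, were miR-330 (at least 15.24 higher), miR-155 (14.77), miR-490 (6.44), miR-687 (6.43) and miR-1951 (5.55). The 5 earliest in the neonate included miR-449b, bounded at -17.86, and an assay named for rat miR-673 at -14.10. The others were the row L assays miR-539, miR-532-5p and miR-532-3p at -16.64, -15.39 and -15.24. miR-155, a miRNA of activated leukocytes, had a Ct of 40 in neonatal room air and of 18.9 to 19.7 in the other 3 libraries.

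Between the hyperoxia libraries, 49 assays were at least 2-fold higher and 222 lower in the adult, of 450, with a median of -0.98 log2. miR-21* was 4.84 higher, miR-29c 3.94, miR-29b 3.76, miR-29a* 3.32, miR-29a 2.81, miR-124 2.79, miR-467b* 2.48, miR-489 2.46, miR-338-3p 2.28 and human-named miR-197 2.11. The lowest were rat-named miR-632 at -10.34, miR-673-5p at -9.57, miR-431 at -9.56, miR-542-5p at -9.32, miR-370 at -9.18, miR-433 at -7.68, miR-376a at -7.44 and miR-369-5p at -7.07. With a Ct of 30 or below, 6 assays were detected in the adult alone and 25 in the neonate alone. For the 5 earliest in the adult, bounds against Ct 35 were 21.02 for miR-191, 8.20 for miR-874, 6.65 for miR-448, 5.54 for miR-211 and 4.54 for miR-147, a macrophage miRNA. For the 5 earliest in the neonate the bounds were -14.35 for rat-named miR-339-3p, -13.73 for rat-named miR-409-5p, -13.57 for rat-named miR-673 and miR-742, and -11.63 for miR-323-3p. The assays of miR-673 and miR-742 hold identical values. miR-191 had a Ct of 40 in neonatal hyperoxia and of 13.3 to 14.4 elsewhere.

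The medians of all assays moved with the scaling. For the room air pair they were 0.26 log2 with mean centring, 1.46 with U6, -0.31 with snoRNA135 and snoRNA202 and 0.40 with each card centred. The counts up and down were then 147 and 110, 248 and 81, 102 and 155, and 171 and 110. For the hyperoxia pair the medians were 0.35, 0.99, -0.44 and 0.41, with counts of 154 and 120, 223 and 114, 78 and 178, and 164 and 123. Against snoRNA202 in room air, U6 itself was at -2.65 on the first card and -1.12 on the second, snoRNA135 at -0.86 and -0.35, U87 at 0.43 and 0.06, and the RNA Y1 at 1.35 and 2.15. Across the 426 assays, which are not independent replicates, the age differences of the 2 pairs correlated at r = 0.761 (Spearman 0.798; 0.812 and 0.735 within the first and second card), and the pairs share no library.

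In neonatal lung after hyperoxia, the inflammation and miR-200 lists stood high among matched random lists, and the airway and alveolar epithelium list did not (percentile 51.6). All 5 measured members of the inflammation list were above 0, 2 of them 2-fold: miR-146b, induced by NF-kB, at 1.47 log2, miR-132 at 1.04, miR-146a at 0.72, miR-212 at 0.57 and miR-21 at 0.13. The list median of 0.72 lay at percentile 99.3 of matched random lists, and the same room air library was the low side of this list's age difference. All 5 members of the miR-200 family, which maintains epithelial identity, were above 0, 1 of them 2-fold, led by miR-200c at 1.21, miR-429 at 0.80 and miR-200b at 0.73 (median 0.73, percentile 97.6). The rat-named assays of 2 of these, which sit on the second card, did not repeat this, with miR-200c at 0.07 and miR-200b at -0.11. That of miR-146b was at 0.82. The random lists were not matched on card. All 5 miR-200 members sit on the first card, where the median of all assays was 0.235, against -0.037 on the second. The miR-200 median of 0.731 lay just above the random lists' upper bound of 0.715, so this percentile cannot be told apart from a card offset. miR-34a, a target of p53, was 1.19 higher. The 3 erythroid miRNAs were below 0, with 0 of them 2-fold lower: miR-451 at -0.91, miR-144 at -0.69 and miR-486 at -0.56 (median -0.69, percentile 0.84). These medians kept their sign under all 6 normalizations, while miR-21 and the miR-200 member miR-141, at 0.13 each, lay below 0 with mean centring and with each card centred.

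Of 5 striated muscle miRNAs 3 were above 0 in that comparison, miR-133a at 1.29, miR-133b at 0.92 and miR-1 at 0.83, while miR-206 was at -1.03 and miR-208b at -0.37 (median 0.83, percentile 98.1). The median is the value of miR-1, whose rat-named assay was at 0.23. These 4 were the only lists of 20 outside the central 95% of random lists, and in simulated unchanged lists 8.5% fell outside it. The let-7 median was 0.32, leukocytes 0.39, the miR-34 family 0.46, endothelium 0.29, hypoxia and redox 0.26, other imprinted loci 0.29, embryonic clusters 0.96 and brain 1.15. Near 0 or below lay miR-17 at 0.12, miR-29 at 0.13, miR-30 at 0.09, airway and alveolar epithelium at 0.07, miR-130 at 0.03, Dlk1-Dio3 at -0.02, miR-15 at -0.18 and fibroblast and mesenchyme at -0.23. The medians of miR-17, miR-29, miR-30, airway and alveolar epithelium and miR-130 lay below 0 with mean centring and with each card centred, and those of airway and alveolar epithelium and miR-130 also with U6. The mean was -0.16 for miR-29 and 0.27 for Dlk1-Dio3, opposite in sign to the median. miR-143 was at 0.09, miR-145 at 0.36, miR-181a at 0.18 and miR-181c at -0.66.

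Of 469 assays, 64 were at least 2-fold higher and 40 lower after hyperoxia in the neonate, with a median of 0.13 log2. The split was 78 and 28 with U6, 61 and 41 with snoRNA135 and snoRNA202, 56 and 44 with mean centring and 50 and 47 with each card centred, with medians of 0.28, 0.09, 0.02 and -0.03. The largest single values above 0 were miR-673-5p at 5.67, miR-511, encoded in the macrophage gene Mrc1, at 4.33, miR-668 at 2.69, miR-423-5p at 2.51, miR-466j at 2.51, miR-423-3p at 2.24, miR-467a* at 2.18, miR-29c* at 1.95, miR-208a, from a cardiac myosin gene, at 1.82 and miR-501-3p at 1.76. The lowest were miR-1896 at -10.57, miR-1982.2 at -5.30, miR-671-5p at -5.19, miR-338-5p at -3.96, miR-2136 at -3.19, miR-376b at -2.62, miR-297c at -1.90, miR-1894-3p at -1.77, human-named miR-197 at -1.66 and miR-196a at -1.59. With a Ct of 30 or below, 12 assays were detected only after hyperoxia and 3 only in room air. The 5 earliest after hyperoxia, with bounds against Ct 35, were miR-155 (14.83), miR-1951 (8.22), miR-139-3p (7.03), the liver miRNA miR-122 (6.88) and miR-687 (6.73). Detected only in room air were miR-191 (-21.10), miR-449b (-17.76) and miR-133a* (-5.83). For miR-155, miR-191 and miR-449b a single library stood apart from all the others. An error of that well cannot be told apart from an effect of hyperoxia. At a mean Ct of 25 or below 11.7% of assays differed 2-fold, against 50.5% at a mean Ct over 28.

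**Figure D3:**
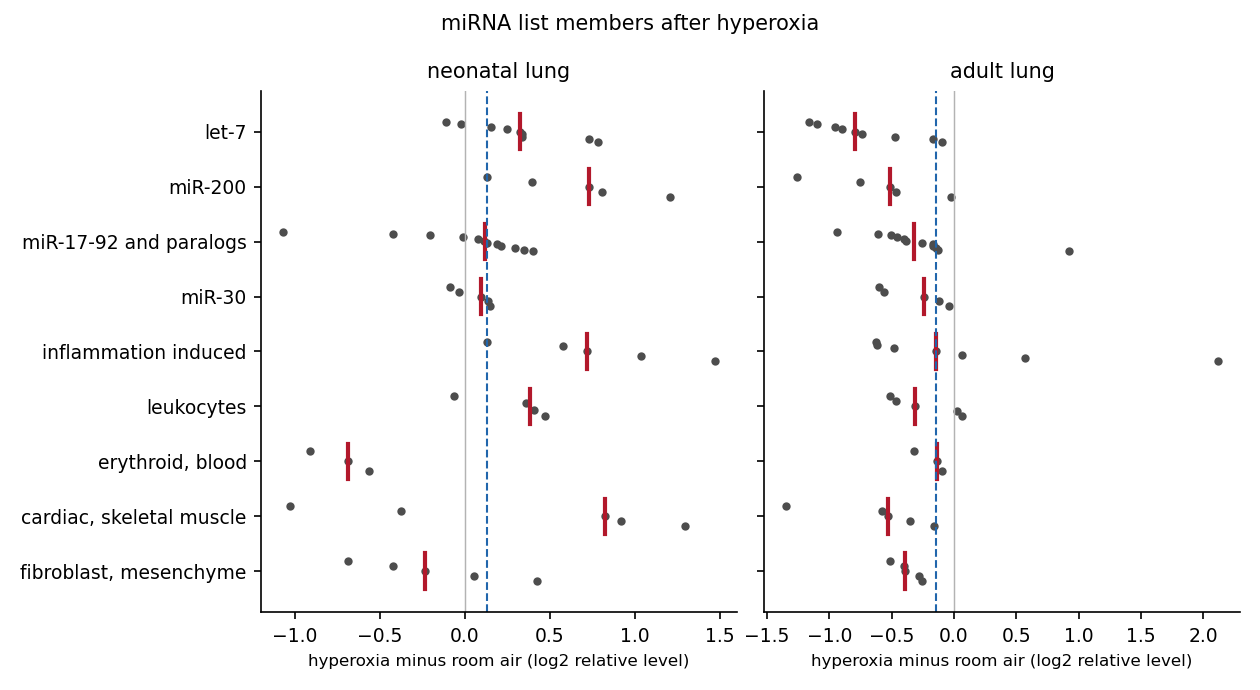
Hyperoxia minus room air log2 relative level of members of 9 miRNA lists in neonatal (left) and adult lung (right), 1 point per assay detected in both libraries. Red bars are list medians, such as 0.32 and -0.80 for let-7 and 0.73 and -0.51 for miR-200. The adult miR-200 median was 0.15 with mean centring and -0.19 with each card centred. The dashed line is the median of all assays, 0.13 in the neonate and -0.14 in the adult.

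In adult lung after hyperoxia, the let-7 family, miRNAs that accompany differentiation, stood low among matched random lists. On the snoRNA202 scale all 9 members were below 0, with let-7e at -1.16, miR-98 at -1.10, let-7f at -0.95, let-7g at -0.90 and let-7a at -0.80. The list median of -0.80 lay at percentile 0 of matched random lists. It stayed below 0 under all 6 normalizations, at -0.47 with each card centred. It was closest to 0 at -0.13 with mean centring, which is less than the technical SD of 0.33. All 9 members sit on the first card, where the median of all assays was -0.292, against 0.069 on the second. The random lists were not matched on card, so a card offset may add to this percentile. Mean centring did not align the cards, with medians of 0.375 and -0.194. Of the members, let-7b and let-7i lay above 0 with mean centring, U6, snoRNA135 and snoRNA202 and each card centred, and let-7d with mean centring. All 5 miR-200 members were also below 0, led by miR-200c at -1.26 and miR-200b at -0.76 (median -0.51, percentile 5.1). The miR-200 median was 0.15 with mean centring and -0.19 with each card centred. The rat-named assays, which sit on the second card, stood above 0, miR-200c at 0.18 and miR-200b at 0.24. miR-28, a member of the hypoxia and redox list, was at -1.07, and miR-210 was at 0.10. The inflammation list had a median of -0.15, which turned to 0.31 with mean centring, 0.10 with U6, 0.11 with snoRNA135 and snoRNA202 and 0.18 with each card centred, and a mean of 0.13. In it, miR-147 was at 2.12, miR-212 at 0.57, miR-155 at 0.07, miR-146b at -0.15, miR-21 at -0.49, miR-146a at -0.62 and miR-132 at -0.62.

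No list besides let-7 lay outside the central 95% in the adult. Muscle stood at a median of -0.53 (miR-133a at -0.57, miR-208b at -1.35), hypoxia and redox at -0.46, fibroblast and mesenchyme at -0.40, miR-15 at -0.37, miR-17 at -0.32, miR-130 at -0.31, leukocytes at -0.31, miR-29 at -0.30, airway and alveolar epithelium at -0.30, miR-30 at -0.24, other imprinted loci at -0.23, Dlk1-Dio3 at -0.14, erythroid at -0.13 and endothelium at -0.07. Mean centring left the median of all assays at 0.375 on the first card and -0.194 on the second. With it, every one of the list medians just given was above 0. Those of endothelium, Dlk1-Dio3, other imprinted loci and miR-30 were above 0 with U6, with snoRNA135 and snoRNA202 and with each card centred too, and those of miR-29, airway and alveolar epithelium, leukocytes and miR-130 with each card centred. The embryonic clusters stood at 0.37, brain at 0.74 and the miR-34 family at 0.09, which had a mean of -0.04 and turned to -0.12 with each card's own snoRNA202. miR-122 was 3.95 higher, miR-143 was at -0.23, miR-145 at -0.12, miR-181a at -0.71 and miR-181c at 0.17.

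Of 448 assays, 23 were at least 2-fold higher and 36 lower after hyperoxia in the adult, with a median of -0.14 log2. The split was 30 and 28 with mean centring, 22 and 29 with each card centred, 21 and 31 with U6 and also with snoRNA135 and snoRNA202, and 17 and 37 with each card's own snoRNA202, with medians of 0.14, -0.03, -0.08, -0.07 and -0.24. The highest values were miR-124 at 2.91, rat-named miR-376a* at 2.10, rat-named miR-29b-2* at 1.79, miR-433 at 1.77, rat-named miR-547 at 1.61, miR-1944 at 1.57, miR-1905 at 1.48, miR-211 at 1.41, miR-329 at 1.33 and an assay shared by 3 miR-297 passenger strands at 1.23. The lowest outside row L were miR-1191 and miR-1199, which hold identical values, at -4.61, miR-29b at -4.35, miR-23a at -2.79, miR-673-3p at -2.35 and miR-7a at -2.02. Row L gave miR-511 at -15.71, miR-582-3p at -8.35, miR-543 at -4.94 and miR-574-3p at -4.32. Of 7 assays detected only after hyperoxia, row L also gave 4 of the 5 highest bounds, beside miR-874 (8.29). These were miR-532-5p (15.27), miR-532-3p (14.64), miR-539 (10.82) and miR-542-3p (8.80). Detected only in room air were miR-330 (-16.45), miR-875-5p (-9.10), miR-687 (-7.64) and, in row L, miR-540-5p (-5.79). At a mean Ct of 25 or below 1 assay of 262 was 2-fold higher and 11 lower (4.6%), against 19 and 19 of 95 at a mean Ct over 28.

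The hyperoxia differences of the 2 ages bore little relation to each other. Across the 426 assays detected in all 4 libraries, Pearson's r was -0.103 and Spearman's rho -0.003, across assays that are not independent replicates. Within the first and second card r was -0.206 and -0.015, and rho was of the other sign, at 0.116 and 0.082. miR-200c (1.21 and -1.26), miR-132 (1.04 and -0.62), miR-133a (1.29 and -0.57), let-7f (0.78 and -0.95) and miR-98 (0.73 and -1.10) lay on opposite sides of 0 in neonate and adult, but miR-132 and miR-133a were above 0 in both with mean centring. With no second library per group the difference between the ages could not be tested. Even within an age the hyperoxia differences agreed little. Between arms of one hairpin r was 0.052 in the neonate and -0.083 in the adult. Between mouse and rat-named assays r was 0.426 and 0.136. A correlation near 0 between the ages therefore cannot show that their responses differ.

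Among 391 assays with a Ct of 32 or below in all libraries, the effects of 95 were at least 2-fold apart. The largest gaps, neonatal minus adult, were 20.04 log2 for miR-511, -11.32 for miR-1896, 9.13 for miR-582-3p, -6.34 for miR-671-5p, 5.68 for miR-1191 and miR-1199, 5.47 for miR-673-5p, -5.16 for miR-1982.2, 4.86 for miR-574-3p and 4.77 for miR-543. Row L holds 4 of these assays, miR-511, miR-582-3p, miR-574-3p and miR-543, and without it r was 0.02.

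**Figure D4:**
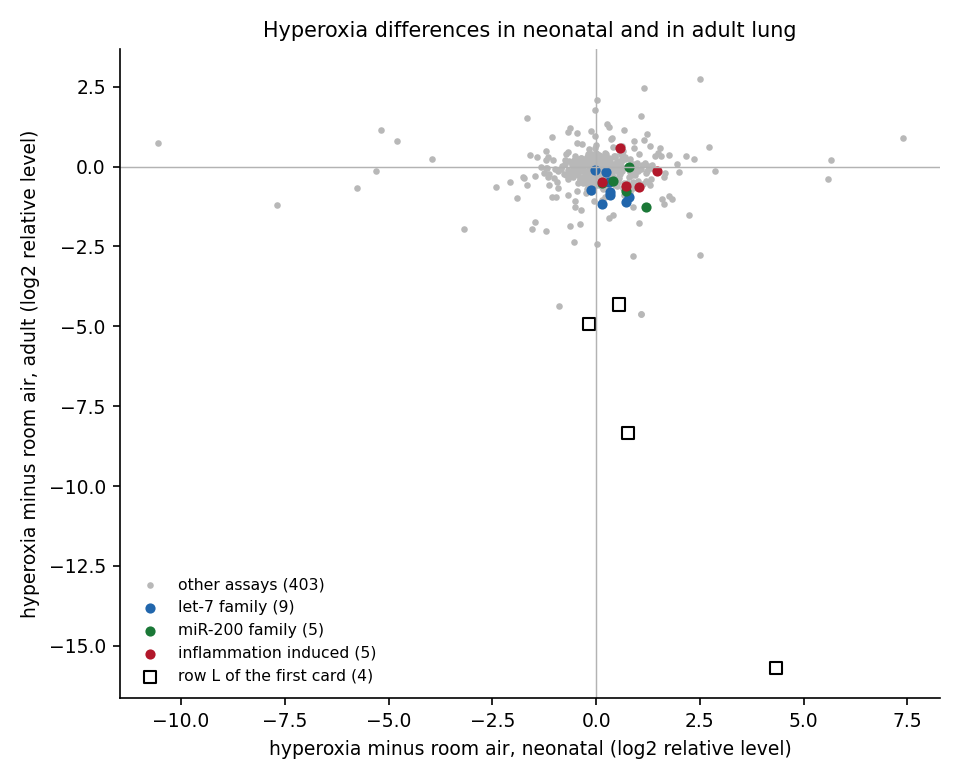
Hyperoxia minus room air log2 relative level in neonatal (x axis) against adult lung (y axis), 1 point per miRNA assay detected in all 4 libraries. The cloud shows no shared trend (r = -0.103), which cannot show that the responses differ. Members of let-7 and miR-200 lie mostly at the lower right, though with mean centring the adult miR-200 median is 0.15. Squares mark 4 assays of row L of the first card.

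Taken over both ages, no miRNA passed the test for hyperoxia. In the limma model of age and oxygen 0 of 426 assays rose and 0 fell (smallest Benjamini-Hochberg adjusted p = 0.963), and 13 had an unadjusted p under 0.05. No list had a call when adjusted over the list alone. miR-423-5p had the smallest unadjusted p and was 2.63 ± 0.25 log2 higher (SE; limma, adjusted p = 0.963), and miR-7a was at -1.61 and miR-219 at 0.99. The model has 1 residual degree of freedom and takes any difference between the ages' responses as error.

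**Figure D5:**
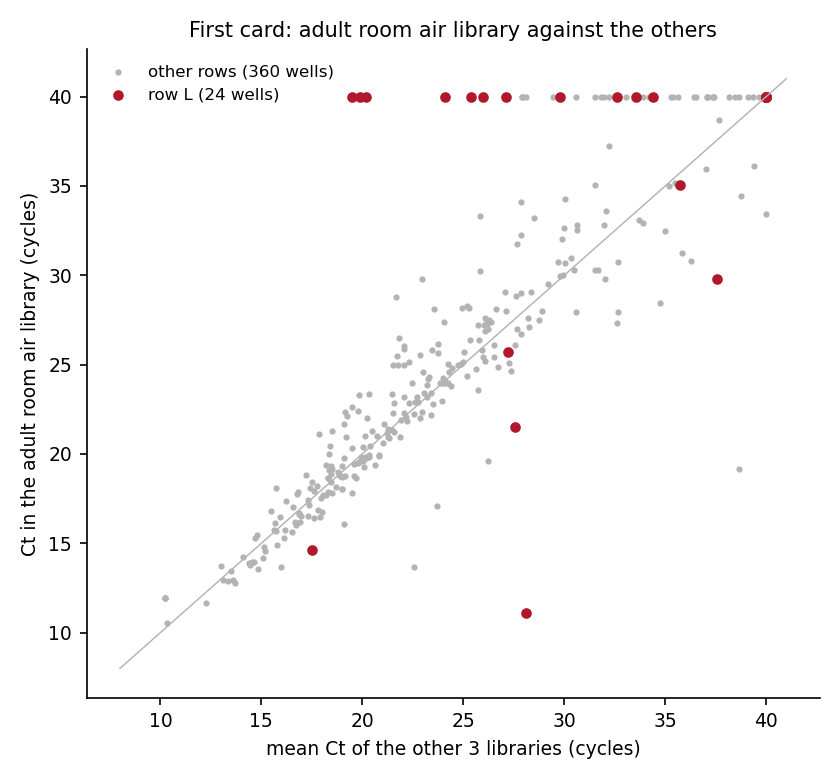
Ct of the first card's wells in the adult room air library (y axis) against their mean in the other 3 libraries (x axis), in cycles; the line marks equal values and 40 stands for no threshold crossed. The 24 wells of row L (red) leave the line on both sides, with r = 0.302.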

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

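The tests on row L were chosen after the row was seen to be out of step, the one on displaced orders before its own result was known. Of the 39 assays named for a hyperoxia comparison, 6 were at least 2-fold higher after hyperoxia at one age and at least 2-fold lower at the other. The difference between the ages was not tested, since each age has 1 library per oxygen condition.

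miR-208a, from a cardiac myosin gene, was at 1.82 log2 in the neonate and -1.004 in the adult, a gap of 2.825. Its adult fall was under 2-fold with mean centring, with U6, with snoRNA135 and snoRNA202, and with each card centred. miR-423-3p was at 2.24 and -1.501, a gap of 3.744. miR-671-5p was at -5.19 and 1.14, a gap of -6.335. Its adult rise was under 2-fold with each card's own snoRNA202 and under every other normalization than the authors' values. miR-1191 and miR-1199 were both at 1.07 and -4.61, a gap of 5.681 for each. Their assays sit in different wells of the second card and hold identical Ct values in all 4 libraries, 29.73, 27.96, 26.64 and 31.59. The neonatal rise of both was under 2-fold with each card centred.

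miR-511, encoded in the macrophage gene Mrc1, had the widest gap, 20.042, from 4.33 in the neonate to -15.71 in the adult. Its Ct was 11.1 in adult room air and 26.2 to 31.5 in the other 3 libraries. The well lies in row L of the first card, and 14 of the row's 24 wells (58.3%) differed by 4 or more cycles between the adult libraries, against 18 of 360 wells (5.0%) in the other rows of that card, a ratio of 11.67. A difference in RNA between the adult lungs as the cause of the row is contradicted by a test that allows for the row having been picked. When the card's 32 such wells were placed at random 10000 times, no row held more than 9 of them (share 0.0001, the smallest that can be had), and in the neonatal pair and the age pair in hyperoxia, where related miRNAs can share a row, the fullest rows held 3 and 11. Failed amplification as the only cause is contradicted, because 6 wells of the row crossed 3 or more cycles earlier than in adult hyperoxia. A displacement of the whole row is contradicted too: in place the row correlated with the mean of the other libraries at 0.302, and shifted along the row, reversed or set against any other row of both cards, 78 orders in all, it reached at most 0.405, against 0.769 or more for every other row of every library in place. What put the row out of step stays open.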

How the results depend on the processing

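The count of assays changed with oxygen over both ages stayed 0 in each direction under every alternative run (limma; 13 at an unadjusted p under 0.05 in the main setting). Ct limits of 32 and 40, eBayes with a trend, each card's own snoRNA202 and the omission of row L left most results in place; the last 2, the limit of 25 and the list medians with each card centred were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers; for the same reason no library could be left out with a residual degree of freedom remaining. For the changes below the cause was not tested, except that the limit of 25 leaves fewer assays to count.

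With mean centring, the assays at least 2-fold higher and lower in the adult were 147 and 110 in room air and 154 and 120 in hyperoxia, and the limma counts for age were 99 up and 77 down. With U6 these counts were 248 and 81, 223 and 114, and 196 and 71. With each card centred they were 171 and 110, 164 and 123, and 136 up, and with snoRNA135 and snoRNA202 the hyperoxia pair had 78 higher and the limma fit 50 up. With a Ct limit of 25 the 2-fold counts were 15 and 13 for neonatal hyperoxia, 1 and 7 for adult hyperoxia, 30 and 85 for age in room air and 13 and 105 for age in hyperoxia, and the limma counts were 12 and 74. A limit of 32 left 13 higher after adult hyperoxia, and no limit below 40 left 10 up with age in limma.

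Of the list medians of 1 log2 or more between the ages, these reversed. In room air, the miR-17 cluster with its paralogs went to 1.58 with U6 and 0.071 with each card centred, the erythroid list to 0.29 with mean centring, 1.62 with U6 and 0.11 with each card centred, the embryonic clusters to 1.31 with U6 and the miR-130 family to 0.75 with U6. In hyperoxia, U6 gave 1.66 for miR-17, 1.42 for fibroblast and mesenchyme, 1.80 for muscle, 1.70 for the embryonic clusters and 0.59 for miR-130. Centring each card gave 0.35, 0.11, 0.49 and 0.39 for the first 4 of these, and mean centring gave 0.08 for muscle. Of the medians nearer 0, those of miR-15, endothelium and fibroblast and mesenchyme in room air, and of let-7, miR-15, miR-200, airway and alveolar epithelium, endothelium, hypoxia and redox and the erythroid list in hyperoxia, went from below 0 to above it with U6 and with each card centred. Mean centring did so for miR-15 in both and for the others in hyperoxia, and snoRNA135 with snoRNA202 for miR-15 in both and for airway and alveolar epithelium and hypoxia and redox in hyperoxia.

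Across assays, the hyperoxia effects of the 2 ages correlated at a Pearson r of 0.02 without row L. Their Spearman rho was 0.12 with mean centring, 0.081 with U6, 0.11 with snoRNA135 and snoRNA202 or with each card centred, 0.056 with own-card snoRNA202 and -0.13 with the limit of 25. The age differences of the room air and hyperoxia pairs had a Pearson r of 0.703 with no limit below 40, 0.831 without row L and 0.892 with the limit of 25, and a Spearman rho of 0.863 with U6, 0.743 with no limit and 0.843 with the limit of 25. Of 160 values of single miRNAs and lists, 73 moved by less than the technical SD with U6, 78 by more, and 9 with a difference of 2-fold or more reversed. With mean centring 80 moved by less, 78 by more and 2 reversed, with each card centred (lists alone) 40 by less, 34 by more and 6 reversed, and with a Ct limit of 32 only 1 by more. With snoRNA135 and snoRNA202 or own-card snoRNA202 all 160 moved by less, as did the 152 recomputed without row L. Differences were wider at a late Ct, whether from error or not: over a mean Ct of 28 the robust SD of a difference was 1.36 in the neonate and 1.15 in the adult after hyperoxia, against 0.44 and 0.37 at 25 or below.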

Other observations

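Of the tests in this part, the one on control RNAs was chosen after the result was seen, as were the comparisons of mouse with rat-named assays and of single wells; the other tests were set before their results.

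Among runs of neighbouring miRNA genes outside the Dlk1-Dio3 list, one stood well below the median of all assays in adult lung. The X-linked run of miR-322, miR-351, miR-450b-3p and miR-503 had a median of -3.22 log2 over 6 assays between the room air libraries and -3.51 between the hyperoxia libraries, with values from -7.03 to -1.88 in room air. Under all 6 normalizations the fits of miR-351 and miR-503 stayed below 0, at -4.00 and -2.37 or lower, as did those of miR-322* and miR-503*, whereas miR-322 reached 0.52 and miR-450b-3p 0.07. Other runs lay nearer the median of all assays, -0.72 in room air: miR-17, miR-19a and miR-20a at -1.34, miR-182, miR-183 and miR-96 at -1.24, miR-106a, miR-20b and miR-363 at -1.10, and miR-106b, miR-25 and miR-93 at -0.88. Some runs were spread widely, such as miR-291a-3p to miR-295, from -2.28 to 3.39. The runs of miR-23b with miR-27b and of miR-23a with miR-27a stood at 0.61, the second with values from 0.35 to 6.92. With U6, miR-17 and its paralogs as a list lay above 0, at 1.58.

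Rat-named assays gave a partial repeat of the mouse assays. For 27 miRNAs with both detected in the room air pair, the age differences correlated at r = 0.831 across assays, with a median gap of 1.06 log2 and a largest gap of 3.39, that of miR-10b. miR-136 stood at -5.09 on the mouse and -5.03 on the rat-named assay, miR-409-3p at -4.99 and -5.54, miR-351 at -7.03 and -5.62, and miR-489 at 3.83 and 3.00. miR-207 was at 2.08 and -1.28 and miR-494 at -2.49 and -5.64. After hyperoxia the corresponding correlations were 0.426 in the neonate over 34 miRNAs and 0.136 in the adult over 27. For miR-200c the mouse assay, on the first card, gave 1.21 and -1.26 in neonate and adult. The rat-named assay, on the second card, gave 0.07 and 0.18 and did not repeat the opposite response. The card medians of all assays were 0.235 and -0.037 in the neonate and -0.292 and 0.069 in the adult. They lay apart in the same direction as the assays, so this pair does not settle the response. For miR-146b the neonatal values were 1.47 and 0.82, but its age differences in room air were 1.94 and 0.13.

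A hypothesis was that neighbouring miRNA genes are expressed together and so differ together with age. Over 44 pairs of genes within 10 kb outside the Dlk1-Dio3 list, the median gap between neighbours' age differences was 1.198 log2 in room air. Random pairs had a median gap of 1.70 with a 5th percentile of 1.239, so the neighbours lie just below it, consistent with the hypothesis by a small margin. That margin is smaller than the distance between the medians of the 2 cards in this pair, -0.394 and -1.197. Whether sharing a card adds to the likeness of neighbours was not tested. A second hypothesis was that both arms of a hairpin differ together. Without the Dlk1-Dio3 list the arms' age differences correlated at r = 0.422 in room air and 0.587 in hyperoxia, between the bounds of 0.2 and 0.5 set for the room air value, so the first value leaves it open.

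Most assays lay lower in adult than in neonatal lung on the snoRNA202 scale, with a median of -0.72 in room air. The adult room air library's use of one card's snoRNA202 for both cards is not the whole cause, as the median with each card's own reference was -0.574. The fall of the Dlk1-Dio3 list is not the whole cause either, as the median without it was -0.578. A difference of snoRNA202 itself with age stays open: of 6 values of snoRNA135, U87 and Y1, 2 lay below 0 and the others above, so the control RNAs do not move as one. U6, left out of that count, was below 0 on both cards, at -2.65 and -1.12. With no reference at all the median was 0.46 in room air and -0.21 in hyperoxia. Lung development is a further explanation, untested.

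After hyperoxia 22.2% of assays differed 2-fold in the neonate and 13.2% in the adult. Error of late assays may account for many of these, since the share was 4.32 times higher at a mean Ct over 28 than at 25 or below in the neonate and 8.70 times higher in the adult. Error independent of Ct may add to it: the arms of one hairpin, which share a precursor, correlated at only 0.052 in the neonate and -0.083 in the adult. The pairs of arms were not split by Ct, so these correlations cannot tell such error from that of late assays. An offset of a card or its reference is contradicted as the whole cause. With each card centred 86.4% as many 2-fold differences were counted in the adult and 93.3% in the neonate. Under all 6 normalizations 16 assays stayed 2-fold higher and 26 lower in the adult, and 50 and 26 in the neonate. An offset may account for some adult calls: with each card's own snoRNA202 the rises went from 23 to 17 and the falls from 36 to 37. An effect of hyperoxia stays open and was not tested apart from error, as each group has 1 library.

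Single wells stood apart outside row L, and whether from an error of the well or from RNA was not tested. In neonatal room air miR-155, miR-124 and rat-named miR-547 had a Ct of 40, with values between 18.9 and 29.8 in the other libraries. miR-449b was at 17.8 in neonatal room air and at 38.9 or 40 elsewhere, and miR-1896 at 15.99 against 25.9 to 27.6. miR-191 had a Ct of 40 in neonatal hyperoxia alone, while its passenger strand miR-191* was detected in all 4 libraries. miR-673-5p had a Ct of 19.0 in neonatal hyperoxia against 25.4 to 27.7. miR-330 was at 19.1 in adult room air and at 36.8 or later elsewhere, and miR-874 at 26.1 in adult hyperoxia and 40 elsewhere.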
